A study of Junonia coenia with 20 samples.

How the data were processed

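Gene expression was measured by RNA sequencing in hind wings of the common buckeye butterfly, Junonia coenia, a nymphalid whose ventral hind wing colour depends on the season. The labels name 2 colour morphs, Linea and Rosa, and 4 stages: the imaginal disc of the 5th larval instar, the pupal wing before pigment, the wing during early (yellow) ommochrome deposition and the wing during late (orange to red) ommochrome deposition. Ommochromes are the tryptophan-derived yellow, red and brown pigments of nymphalid wings. Per the labels' protocols, animals were reared under short, cool days (21°C, 8 h of light) or long, warm days (27°C, 16 h of light). The labels do not state which morph came from which regime. In this species Rosa is generally known as the dark red form of cool, short days and Linea as the tan form of warm, long days. If the animals here followed that pattern, a morph difference cannot be told from a difference in rearing temperature and day length.

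Per the labels' protocols, polyadenylated RNA was amplified into double-stranded cDNA with the Ovation RNA-seq system, sheared to 300 bp and sequenced as paired-end reads of 75 bp or 100 bp. The series description names a pair of Illumina instruments, GAII and HiSeq 2000, and the labels used here do not say which library was read on which. The labels do not say whether a replicate is a single animal, a pool or a repeat preparation, so p-values measure only the spread between these libraries, which may be technical.

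The deposited values are RPKM, reads divided by transcript length and by library size, made by the authors against a de novo transcriptome. Reads were aligned with Bowtie 0.12.7, per the submitters' processing notes. The assembler, the RPKM estimator and any filter on transcripts are not given in the sources used here. The table lists 16251 transcripts under identifiers of the authors' assembly, with no gene names, coordinates, lengths or sequences, and no genome or name table was used here. For that reason the 19 gene lists fixed in advance (pigment pathways, wing patterning, hormone response, cuticle, cell cycle, clock, heat shock and markers of other cell types, among others) could not be matched to transcripts, and no list was tested. Transcripts are reported by identifier, and nothing is said of what they encode.

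The labels describe 20 samples, and 16 of them have a column of values. The other 4 (Linea larva replicate 1, Linea early ommochrome replicate 3, Rosa larva replicate 1 and Rosa early ommochrome replicate 2) were not analysed here. Every morph and stage was thus represented by 2 libraries. No replicate pair held identical values.

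RPKM keeps no read count, so the sequencing depth of each library is unknown, and no counting interval or detection limit is given. The low values were searched for steps that would mark whole reads. Ratios of low values between libraries did not gather at fixed steps (at most 0.547% of ratios fell in any bin), and 2595 values lay above 0 and below 0.001 RPKM. Reads were thus shared out as fractions, and no count test was run.

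Values were scaled by library, because the median RPKM differed more than 2-fold between libraries. The scaling factor was the median log2 ratio to the geometric mean over the 7126 transcripts at 1 RPKM or more in every library. "Scaled RPKM" below means the deposited RPKM divided by this factor. Transcripts at 1 RPKM or more in at least 2 libraries were kept (15798 of 16251). Tests used limma 3.58.1 in R 4.3.3 on log2(scaled RPKM + 1), with a mean for each of the 8 groups, all 16 libraries in a single fit (8 residual degrees of freedom), moderated variances with an intensity trend, and Benjamini-Hochberg adjustment over the 15798 transcripts. The threshold was an adjusted p of 0.05. Fold changes are on the log2(scaled RPKM + 1) scale, which understates changes of low transcripts. The 9 comparisons were Rosa against Linea at each stage and averaged over stages, each step between successive stages averaged over morphs, and an F test of whether the morph difference varied with stage. The steps within Linea and within Rosa were tested in the same fit and are not among these 9.

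These 9 comparisons, the thresholds and the alternatives were fixed before the data were examined, except where stated. The rule for naming transcripts was to give, per comparison, at most 2 that rose and 2 that fell. These were the largest changes past the threshold with a mean of at least 5 scaled RPKM in the higher group and no overlap between groups. Where a comparison called 5 or fewer transcripts, those outside the rule are named as well and marked as such. The alternatives were RPKM as deposited, quantile normalization, a pseudocount of 0.1, no low-value filter, a mean of at least 5 RPKM, the replicate number as a block, array weights, a 2-fold minimum, fits on the compared libraries alone and the removal of each library in turn.

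Counts of transcripts that keep a change at a later or earlier stage share libraries with the test that picked the transcripts. They were therefore also taken with the calls of each morph and the course of the other, and in 100 simulated sets of unchanged groups, in which each library received the deviations of a randomly drawn library. The calls of each morph still rest on a spread estimated from all libraries. These checks were added after seeing the data. The fit was tested on simulated data for 15798 transcripts, made from the real means and within-group differences with planted changes of known size. Changes were planted only in the more abundant transcripts, so recovery among low ones was not measured. Deviations were drawn for each transcript separately, so shared deviations of a whole library were not simulated. For Rosa against Linea in larvae (2 against 2 libraries) it recovered 25.3% of planted 8-fold changes, 8.7% of 4-fold changes and none of the 2-fold changes, with 7 false calls. For the morph difference averaged over stages it recovered 90.8% of 8-fold, 66.7% of 4-fold and 19.7% of 2-fold changes, with 10 false calls. For early to late ommochrome it recovered 74.6% of 8-fold, 39% of 4-fold and 1.67% of 2-fold changes, with 7 false calls. For larva to pre-pigment, 67.1% of 8-fold and 27.6% of 4-fold changes were recovered, with 1 false call.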

Results

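Hind wing transcript levels were compared between the Linea and Rosa colour morphs of J. coenia at 4 stages, from the larval imaginal disc to late ommochrome deposition, with 2 libraries per morph and stage. The design asks which transcripts differ between the seasonal morphs, at which stage, and how expression changes as the wing develops. The sum of RPKM over the listed transcripts ranged from 487429 in Linea early ommochrome replicate 2 to 832300 in Linea larva replicate 3. Between 11339 and 14314 transcripts reached 1 RPKM per library.

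Larval discs stood apart from all pupal wings. Principal component 1 held 34.5% of the variance and placed the 4 larval libraries between -152.9 and -111.2 and the 12 pupal libraries between 28 and 63.3. The median Spearman correlation between a larval and a pupal library was 0.565, against 0.758 between libraries of 2 different pupal stages. Libraries of the same morph and stage had a median correlation of 0.788, and libraries of the same stage but of the other morph had 0.786. The pre-pigment libraries numbered 1 separated from the others on principal component 2, at 141.1 in Rosa and 62.3 in Linea. The same-stage libraries numbered 2 lay at -15.9 and -1.5.

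Expression was concentrated in fewer transcripts in pupal wings. The 10 most abundant transcripts of a library held 10.89% ± 2.32 (SD, n = 4) of the summed RPKM in larvae. They held 31.72% ± 2.061 (SD, n = 4) in pre-pigment wings, 25.44% ± 5.439 (SD, n = 4) at early ommochrome and 22.88% ± 6.655 (SD, n = 4) at late ommochrome. Each pupal stage exceeded larvae in an exact two-sided permutation test (p = 0.02857 for each of 3 comparisons, adjusted p = 0.02857), the smallest value that 4 against 4 libraries allow. The median transcript of a library was at 9.561 ± 1.07 RPKM (SD, n = 4) in larvae and 4.209 ± 0.5396 RPKM (SD, n = 4) in pre-pigment wings. Scaling removed this difference, so changes in scaled values below are relative to the median transcript.

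**Figure D1:**
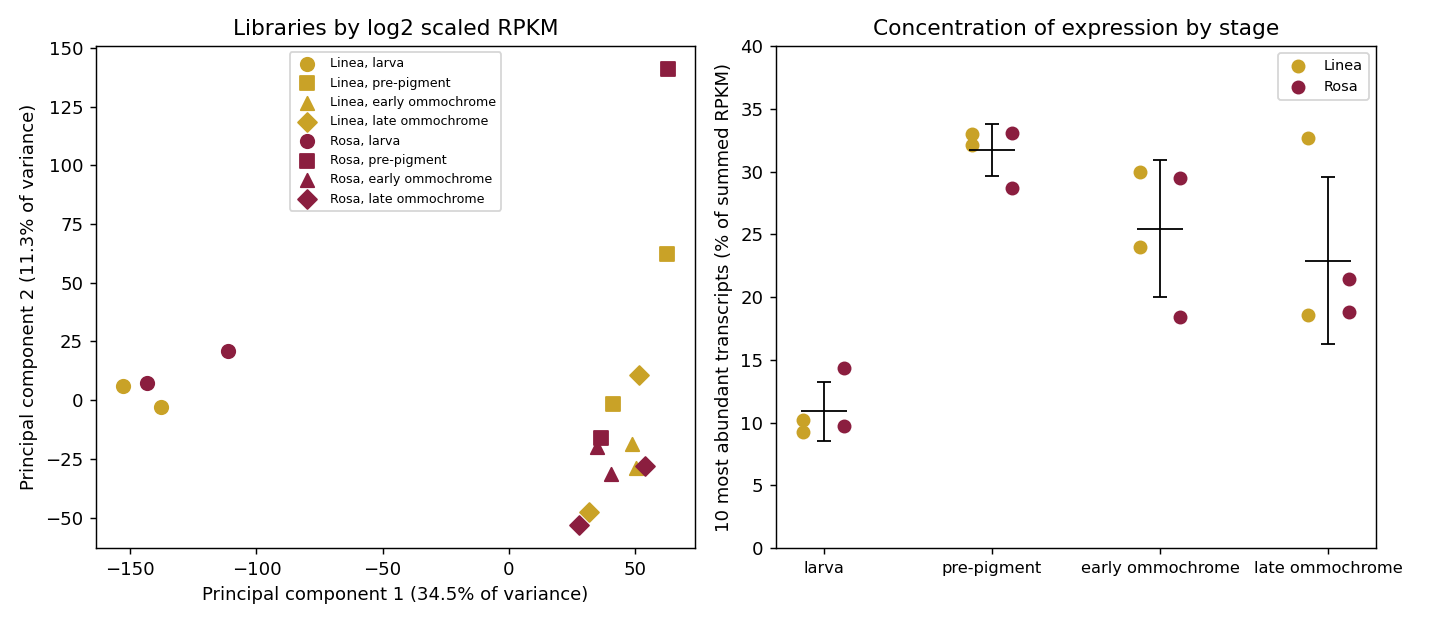
Left, the 16 libraries on principal components 1 and 2 of log2 scaled RPKM; colour gives the morph and symbol the stage. Right, share of summed RPKM (%) in the 10 most abundant transcripts of each library, with the mean and SD of the 4 libraries per stage as bars; the larval libraries lie between 9.252% and 14.32%, below every pupal library.

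The step from larva to pre-pigment pupa changed the most transcripts. With both morphs averaged, 2107 transcripts rose and 2274 fell (limma, adjusted p under 0.05, 15798 tested). JC_0066288 rose from 0.0979 ± 0.186 to 418 ± 215 scaled RPKM (SD, n = 4 each), a log2 change of 8.47 ± 0.64 (SE, limma adjusted p = 8e-06). JC_0032639 rose from 14 ± 9.52 to 2430 ± 926 scaled RPKM (SD, n = 4 each), a log2 change of 7.5 ± 0.57 (SE). At early ommochrome it was at 2370 ± 447 scaled RPKM in Linea but 57.2 ± 38.3 in Rosa (SD, n = 2 each). It is among the 20 transcripts low in Rosa early ommochrome whose source is left open below. JC_0062905 fell from 2980 ± 2790 to 1.72 ± 1.6 scaled RPKM (SD, n = 4 each), a log2 change of -9.91 ± 0.88 (SE, limma adjusted p = 1.8e-05). JC_0062502 fell from 3850 ± 1840 to 40.7 ± 44.9 scaled RPKM (SD, n = 4 each), with a log2 change of -7.65 ± 1.18 (SE). Single libraries moved the fold of these fallers: JC_0062905 was at -9.3 and -10.49 without Linea larva replicates 2 and 3. JC_0062502 was at -6.53 and -8.76 without Linea pre-pigment replicates 1 and 2, and at -6.61 and -8.66 without the Rosa ones.

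Most of these changes were still present at the last stage. Of the 2107 transcripts that rose, 1644 (78%) were at least 2-fold above the larval mean at late ommochrome, and 457 were within 2-fold of it. Of the 2274 that fell, 1733 (76.2%) were at least 2-fold below the larval mean at late ommochrome, and 540 were within 2-fold. These counts share the larval libraries with the test that picked the transcripts, and in simulated unchanged groups the shares had medians of 14.7% (highest 55.2% of 100 draws) and 11.9% (highest 80.6%). With calls from Linea and the course from Rosa, which share no library, 955 of 1292 risers (73.9%) and 730 of 1092 fallers (66.8%) kept the 2-fold difference at late ommochrome, against 21.9% and 20.2% of all transcripts. JC_0062905 stayed low, at 1.08 ± 0.0649 scaled RPKM in Linea and 6.08 ± 8.33 in Rosa at late ommochrome (SD, n = 2 each). JC_0066288 was at 23.8 ± 6.82 in Linea and 4.65 ± 6.37 in Rosa by then (SD, n = 2 each).

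The larva to pre-pigment changes recurred between morphs, which share no libraries. In Linea alone 1292 transcripts rose and 1092 fell, and in Rosa alone 973 rose and 635 fell (limma, adjusted p under 0.05). Of the Linea risers, 1256 (97.2%) also had a higher mean in Rosa pre-pigment wings, and 763 passed the threshold in both morphs, where independent lists would share 79.6. Of the Linea fallers, 1039 (95.1%) had a lower mean in Rosa, and 351 passed in both, against 43.9 for independent lists. Both lists came from the same fit of all libraries and share its estimate of each transcript's spread. They are thus not independent, and part of the excess may reflect that. Across transcripts the log2 changes of the morphs had a Pearson correlation of 0.74 and a Spearman correlation of 0.68; transcripts are not independent replicates. The Linea count of 2384 became 860 and 1057 without Linea larva replicates 2 and 3, and 1068 and 1282 without Linea pre-pigment replicates 1 and 2. The Rosa count of 1608 became 989 without Rosa larva replicate 3, 899 without Rosa pre-pigment replicate 1 and 696 with array weights. With RPKM as deposited the counts were 4899 and 4795, and fitted on its own 4 libraries Linea gave 1526 calls and Rosa 0.

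The split between risers and fallers depends on the scaling. With RPKM as deposited, the median change from larva to pre-pigment was shifted by -1.081 log2 units, and 1043 transcripts rose while 6892 fell. Larvae have no library numbered 1, so this step partly coincides with the replicate number: with only libraries numbered 2, 715 transcripts rose and 174 fell.

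From pre-pigment pupa to early ommochrome, 36 transcripts rose and 56 fell. All 56 fallers had a pre-pigment mean at least 2-fold above the larval mean, and 44 (78.6%) were within 2-fold of their early level at late ommochrome, as were 89.8% of all transcripts. The first count shares the pre-pigment libraries with the test, and simulated unchanged groups gave a median of 34.8% and up to 100%. With calls from a morph and the course from the other, 11 of 11 Linea fallers were 2-fold above larvae in Rosa pre-pigment wings and 18 of 21 Rosa fallers (85.7%) in Linea ones, against 21.2% and 25.2% of all transcripts. JC_0096614 went from 2.73 ± 1.86 scaled RPKM in Linea larvae to 247 ± 45.2 at pre-pigment and 0.125 ± 0.122 at early ommochrome (SD, n = 2 each). In Rosa the same transcript had 1.53 ± 0.98, 163 ± 42.7 and 1.61 ± 2.22 scaled RPKM (SD, n = 2 each). Its log2 change between the pupal stages was -7.03 ± 0.54 (SE, limma adjusted p = 0.00018). JC_0091895 fell from 533 ± 222 to 4.33 ± 5.61 scaled RPKM (SD, n = 4 each), a log2 change of -7.07 ± 0.69 (SE, limma adjusted p = 6e-04), or -6.34 and -7.79 without Rosa early ommochrome replicates 1 and 3.

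Of the 36 risers, 30 (83.3%) had a late ommochrome mean within 2-fold of the early one, against 89.8% of all transcripts. JC_0049330 rose from 5.63 ± 5.36 to 149 ± 63.7 scaled RPKM (SD, n = 4 each), a log2 change of 4.8 ± 0.58 (SE, limma adjusted p = 0.0033). Its late ommochrome mean was lower than the early one in both morphs, at 75.8 ± 26.6 against 158 ± 108 scaled RPKM in Linea and 17.3 ± 15.3 against 140 ± 11.5 in Rosa (SD, n = 2 each). JC_0002931 rose from 4.77 ± 7.41 to 124 ± 82.8 scaled RPKM (SD, n = 4 each), a log2 change of 4.79 ± 0.94 (SE, limma adjusted p = 0.048). Its log2 change was 3.77 and 5.84 without Rosa pre-pigment replicates 1 and 2 and 5.4 without Linea early ommochrome replicate 1, and with any single library left out it kept its call only without Rosa pre-pigment replicate 2. In Linea alone 3 rose and 11 fell and in Rosa alone 16 rose and 21 fell. All 3 risers and 8 of the fallers called in Linea were also called in Rosa, by the same fit with its shared spread estimate. These calls depend on single libraries and settings. The Linea count was 1 without Linea pre-pigment replicate 2 or early ommochrome replicate 1, 0 without early ommochrome replicate 2, and 34 and 28 without Rosa pre-pigment replicates 1 and 2. The Rosa count was 22 and 615 without those Rosa libraries, 0 and 13 without Rosa early ommochrome replicates 1 and 3, and 16 without Linea larva replicate 2 or 3. Fits on the compared libraries alone gave 0 in each morph, a pseudocount of 0.1 gave 4 in Linea and 5 in Rosa, and array weights gave 55 and 7. With RPKM as deposited, 47 rose and 26 fell, after a shift of the median transcript by 0.341 log2 units. Libraries numbered 1 alone and libraries numbered 2 alone, 6 and 7 libraries, were fitted with additive stage and morph terms and 2 residual degrees of freedom. Those numbered 1 gave 0 calls, and JC_0096614 changed by -7.54. Those numbered 2 hold a single early ommochrome library, Linea replicate 2, and JC_0096614 changed by -7.31 in them. A fit on the compared libraries alone called 12 transcripts (6 up and 6 down) and a pseudocount of 0.1 called 49; JC_0002931 was called in neither, and JC_0049330, JC_0091895 and JC_0096614 in both. The count was 656 without Rosa pre-pigment replicate 2, 28 without Rosa early ommochrome replicate 1, 34 without Linea pre-pigment replicate 2, and 35 and 39 without Linea early ommochrome replicates 1 and 2.

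With both morphs averaged, no transcript passed the threshold from early to late ommochrome. In Linea alone 2 transcripts rose (limma, lowest adjusted p 0.00964; 896 at an unadjusted p under 0.05), and in Rosa alone 0 were called (limma, 650 at an unadjusted p under 0.05). In limma, 843 transcripts had an unadjusted p under 0.05, where 789.9 are expected by chance, and the lowest adjusted p was 0.152. Without Linea late ommochrome replicate 1, or without Rosa late ommochrome replicate 2, 1 transcript was called. The Linea count was 0 without any single Linea library of either stage, except that it was 14 without Linea late ommochrome replicate 2, and it was 0 in a fit on those 4 libraries alone. The log2 changes of this step had a Pearson correlation of -0.03 between the morphs. At this number of libraries 74.6% of 8-fold changes simulated in the more abundant transcripts were recovered.

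**Figure D2:**
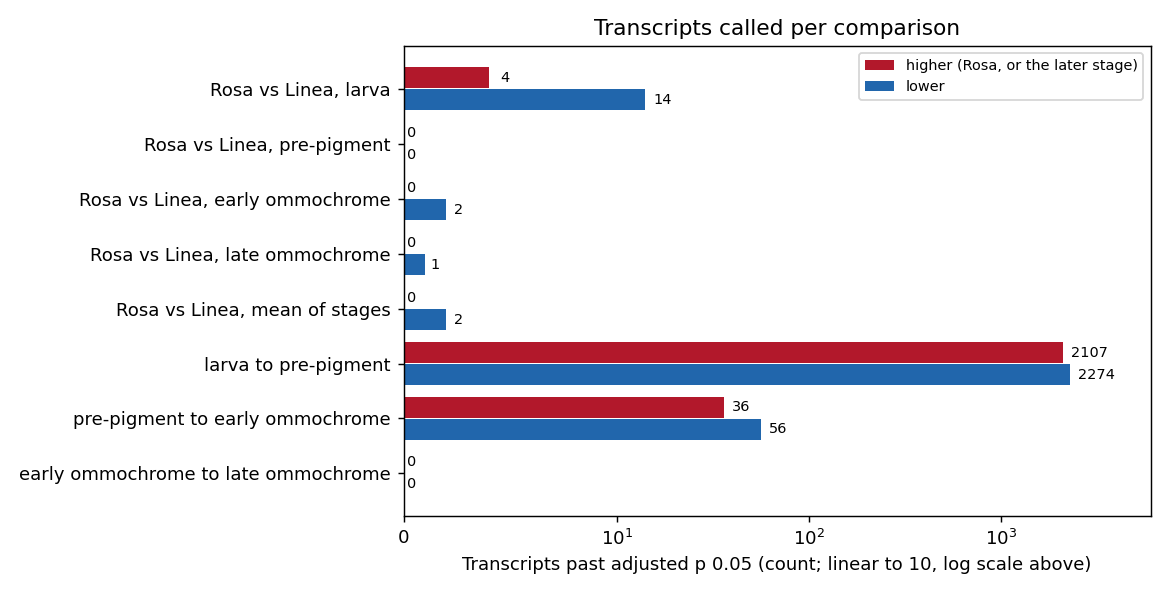
Number of transcripts past an adjusted p of 0.05 in each comparison except the F test (limma; axis linear to 10 and logarithmic above), red for transcripts higher in Rosa or at the later stage and blue for lower. The larva to pre-pigment step gives 2107 and 2274 transcripts, and no morph comparison gives more than 14 in either direction.

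Between the morphs, 4 transcripts were higher and 14 lower in Rosa than in Linea larval discs. JC_0002973 was at 88.6 ± 0.453 scaled RPKM in Linea and 1.03 ± 0.973 in Rosa (SD, n = 2 each), a log2 difference of -5.55 ± 0.58 (SE, limma adjusted p = 0.0037). At the 3 pupal stages its mean was no more than 1.11 in either morph. JC_0020131 was also lower in Rosa, at 0.931 ± 1.32 against 24.1 ± 1.56 scaled RPKM (SD, n = 2 each), a log2 difference of -3.89 ± 0.51 (SE, limma adjusted p = 0.0092), or -4.6 and -3.14 without Rosa larva replicates 2 and 3. JC_0058877 was higher in Rosa, at 17.2 ± 2.4 against 0.876 ± 0.0429 scaled RPKM (SD, n = 2 each), a log2 difference of 3.27 ± 0.4 (SE, limma adjusted p = 0.0076). In pre-pigment wings JC_0058877 was present in both morphs, at 22.7 ± 1.71 in Linea and 34.2 ± 5.69 in Rosa (SD, n = 2 each). JC_0014339 was at 37.6 ± 34.5 in Rosa and 0.958 ± 0.389 in Linea larvae (SD, n = 2 each), a log2 difference of 3.95 ± 0.59 (SE, limma adjusted p = 0.028). Its scaled RPKM was 62 in Rosa larva replicate 2 and 13.2 in replicate 3, and the log2 difference was 2.85 without replicate 2 and 4.99 without replicate 3.

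The larval count depends on single libraries: it was 0 without Linea larva replicate 2, 31 (15 higher and 16 lower in Rosa) without Rosa larva replicate 2 and 169 (141 higher and 28 lower) without Rosa larva replicate 3. The excess of lower transcripts is thus lost without either Rosa larval library, but kept without Linea larva replicate 3. Without Rosa larva replicate 3 the Rosa larvae are replicate 2 alone, which held 111 transcripts far above every other library (described below). A fit on the 4 larval libraries alone gave 0 calls, a pseudocount of 0.1 gave 2 calls of which 1 was shared, and a mean of at least 5 RPKM gave 1. JC_0058877 was called under the latter pair of settings, and JC_0002973, JC_0020131 and JC_0014339 under neither. In the fit of all libraries 1024 transcripts had an unadjusted p under 0.05 against 789.9 expected. Simulated data with planted changes gave 7 false calls in this comparison.

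In pre-pigment wings no transcript differed between the morphs by limma, with 767 at an unadjusted p under 0.05 against 789.9 expected and a lowest adjusted p of 0.346. Without Rosa pre-pigment replicate 2, which leaves Rosa replicate 1 alone, 243 were called.

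At early ommochrome 2 transcripts were lower in Rosa. JC_0062347 was at 1.88 ± 1.72 scaled RPKM in Rosa and 96.5 ± 5.59 in Linea (SD, n = 2 each), a log2 difference of -5.22 ± 0.67 (SE, limma adjusted p = 0.045), or -5.85 and -4.57 without Rosa early ommochrome replicates 1 and 3. At late ommochrome it was at 58.9 ± 1.36 in Rosa and 97.8 ± 72 in Linea (SD, n = 2 each). JC_0050014 was at 0.524 ± 0.732 in Rosa and 39.9 ± 2.78 in Linea (SD, n = 2 each), a log2 difference of -4.83 ± 0.56 (SE, limma adjusted p = 0.033). In the full fit 881 transcripts had an unadjusted p under 0.05 by limma. With array weights 62 were called (11 higher and 51 lower in Rosa). The limma count was 0 with RPKM as deposited, where the median difference was shifted by 0.613 log2 units towards Rosa. The count was 0 with a pseudocount of 0.1 and in the fit on the compared libraries alone. It was also 0 without any single larval, pre-pigment or early ommochrome library, 1 without Rosa late ommochrome replicate 1 and 7 without Rosa late ommochrome replicate 2.

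At late ommochrome 1 transcript was lower in Rosa. JC_0049476 was at 1.83 ± 0.575 scaled RPKM in Rosa and 98.8 ± 17.9 in Linea (SD, n = 2 each), a log2 difference of -5.14 ± 0.56 (SE, limma adjusted p = 0.018). Its mean was at most 2.83 scaled RPKM in the other 6 groups. JC_0049476 lost its call with a mean of at least 5 RPKM (limma adjusted p = 0.0535) and in the fit on the compared libraries alone. The count was 0 without Linea late ommochrome replicate 1, Linea larva replicate 2 or Linea larva replicate 3, and 20 (17 higher and 3 lower in Rosa) without Linea late ommochrome replicate 2. It was 2 without Linea early ommochrome replicate 1 or 2 and without Rosa late ommochrome replicate 1, and a pseudocount of 0.1 called 2 other transcripts, both higher in Rosa.

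**Figure D3:**
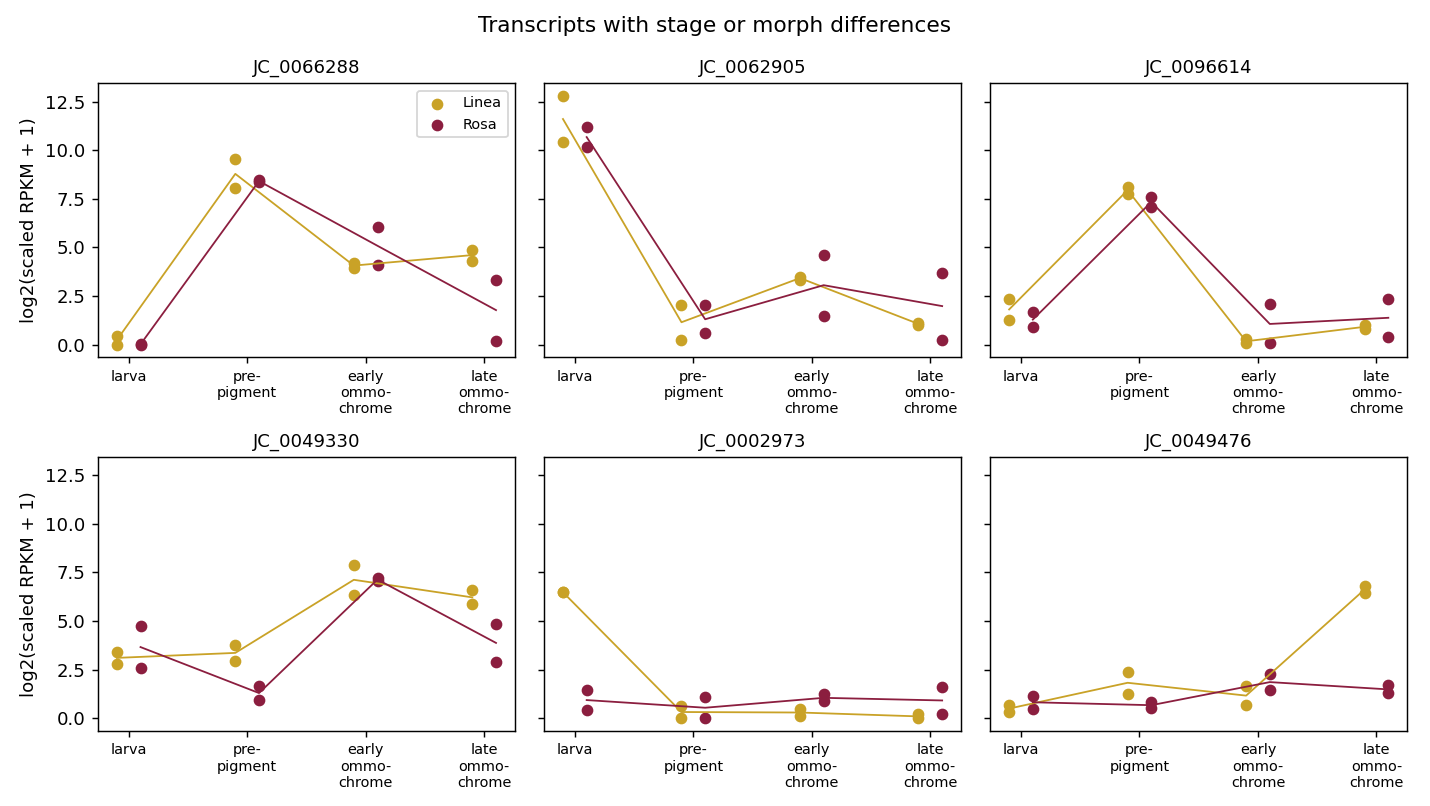
Log2(scaled RPKM + 1) of 6 named transcripts by stage; points are the 2 libraries per morph and lines join their means. JC_0066288 and JC_0096614 peak at pre-pigment in both morphs, JC_0062905 is high only in larvae, JC_0049330 rises at early ommochrome, and JC_0002973 (larva) and JC_0049476 (late ommochrome) have a high mean in Linea at 1 stage.

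Averaged over the 4 stages, 2 transcripts were lower in Rosa, and none was higher. Both lie outside the naming rule, because the morphs' libraries overlap; they are the whole count and were chosen after their values were seen. JC_0050014 had a mean log2 difference of -2.53 ± 0.28 (SE, limma adjusted p = 0.021). It was alike in larvae, at 87.5 ± 6.54 scaled RPKM in Linea and 78.2 ± 11.4 in Rosa, and at late ommochrome it was at 33.5 ± 0.649 and 1.79 ± 2.09 (SD, n = 2 each). JC_0051542 had a mean log2 difference of -2.61 ± 0.32 (SE, limma adjusted p = 0.029). It was listed at 0 in both Rosa libraries of early and of late ommochrome, and at 6.9 ± 4.47 and 10 ± 0.779 scaled RPKM in Linea (SD, n = 2 each).

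The pupal libraries numbered 1 had a larger scaling factor than their partners in 6 of 6 groups (exact two-sided sign test, p = 0.0313). Within libraries numbered 1 and within libraries numbered 2, the averaged morph difference called 0 transcripts. The direction turned without some libraries. Without Rosa larva replicate 3, most calls were higher in Rosa. That fit leaves Rosa larva replicate 2 alone in its group, and this library held 111 transcripts far above every other library (described below). Whether they account for the turn was not tested. The calls were also higher in Rosa without Rosa larva replicate 2 and Rosa pre-pigment replicate 1 together, a setting added after seeing the data. The count was 0 with RPKM as deposited. It was 0 without any single Linea library from larva to early ommochrome other than pre-pigment replicate 2, and without Linea late ommochrome replicate 1, Rosa larva replicate 2, Rosa pre-pigment replicate 1 or Rosa early ommochrome replicate 1. It was 1 without Rosa early ommochrome replicate 3 or either Rosa late ommochrome library. In the fit of all libraries 878 transcripts had an unadjusted p under 0.05 for this comparison, against 789.9 expected. With a pseudocount of 0.1, JC_0051542 kept its call and JC_0050014 lost it (limma adjusted p = 0.177).

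No transcript passed the F test for a morph difference that varies with stage (limma, lowest adjusted p 0.0938; 964 at an unadjusted p under 0.05 against 789.9 expected). A morph difference called at a single stage is thus not shown to differ from that at other stages. The test did call transcripts without Rosa larva replicate 3 and without Rosa pre-pigment replicate 2. Each of these fits leaves a lone Rosa library at that stage, in larvae the replicate 2 with its own high transcripts (described below). Across transcripts, the Rosa minus Linea differences of any 2 stages, which share no libraries, had Pearson correlations between -0.12 and 0.09.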

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

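Fits without 2 doubted libraries and fits within a replicate number were chosen after seeing the data; the other settings were fixed before the data were examined. Depth is unknown for every library, so how far it limits low transcripts cannot be stated. Larva to pre-pigment gave at least 3046 calls, at least 2744 of them shared with the full fit, under all settings except libraries numbered 2 alone (889, 782 shared); as deposited, 3315 of 7935 were shared. The named transcripts had 439 values in other settings. None reversed direction, which the rule of no overlap between groups largely fixed in advance, and 132 fell short of the threshold. Gene list alternatives were not run because transcripts carry no names.

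With RPKM as deposited the counts were 30 for Rosa against Linea in larvae, 0 at early ommochrome, 0 for the average over stages and 7935 for larva to pre-pigment. With a pseudocount of 0.1 they were 2 in larvae, 0 at early and 2 at late ommochrome (0 shared with the full fit), 1 for the average and 49 for pre-pigment to early ommochrome. Quantile normalization and the fit with no low-value filter each left 1 at early ommochrome. A mean of at least 5 RPKM gave 1 in larvae, 7 at early and 0 at late ommochrome. Array weights gave 62 at early ommochrome. Fits on the compared libraries alone gave 0 in larvae, 0 at early and 0 at late ommochrome, and 12 for pre-pigment to early ommochrome; these fits have fewer residual degrees of freedom. For the other settings the cause was not tested.

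Same-numbered Linea and Rosa libraries of a stage had correlated deviations from their group means of 0.17 in larvae, 0.38 at pre-pigment, 0.04 at early and 0.17 at late ommochrome. Because 1 value lies below 0.1, the numbers were not taken to pair the samples. With the replicate block the counts were 0 at early ommochrome, 0 at late ommochrome and 0 for the average, 13 in larvae, 3079 for larva to pre-pigment and 81 for pre-pigment to early ommochrome.

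Without Rosa larva replicate 2 and Rosa pre-pigment replicate 1 together, 20 transcripts were called at early ommochrome and 0 at late ommochrome; the 2 calls of the average over stages were then both higher in Rosa and shared 0 transcripts with the full fit. Libraries numbered 1 alone gave 0 for the average and 0 for pre-pigment to early ommochrome. Libraries numbered 2 alone gave 0 for the average and 889 for larva to pre-pigment. Their count for pre-pigment to early ommochrome is not given, because they hold a single early ommochrome library, Linea replicate 2.

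Leaving out each library in turn, with a lone library assumed to vary like the other groups, gave 0 (without Linea larva replicate 2) to 169 calls (without Rosa larva replicate 3) in larvae. The ranges were 0 to 243 at pre-pigment (highest without Rosa replicate 2), 0 to 7 at early ommochrome (highest without Rosa late replicate 2) and 0 to 20 at late ommochrome (highest without Linea replicate 2). They were 0 to 19 for the average over stages and 0 to 71 for the F test, both highest without Rosa larva replicate 3. For the stage steps they were 3046 (without Linea larva replicate 2) to 4661 (without Rosa pre-pigment replicate 2), 28 to 656, and 0 to 1 for early to late ommochrome.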

Other observations

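In RPKM as deposited, some of the 10 most abundant transcripts were far lower in larvae than in pupal wings and others were not. JC_0048950, the most abundant on average, was at 1000 ± 748 RPKM in larvae, 26600 ± 26100 at pre-pigment, 43900 ± 25100 at early and 31800 ± 27400 at late ommochrome (SD, n = 4 each). JC_0109807 was steadier, at 1220 ± 1250 RPKM in larvae and 16900 ± 1000, 18300 ± 6340 and 16300 ± 1860 at the later stages (SD, n = 4 each). JC_0049716 had its highest mean in larvae, at 10000 ± 3780 RPKM against 4810 ± 2650, 4620 ± 2190 and 5900 ± 2640 (SD, n = 4 each). These values are not scaled, and the mean log2 scaling factor was 0.801 in larvae and -0.522 at pre-pigment. Scaling would lower the larval values and raise the pre-pigment ones. The larval peak is therefore not shown relative to the median transcript. Few transcripts were restricted to a stage. With at least 5 scaled RPKM in all 4 libraries of a stage and under 1 elsewhere, there were 7 in larvae, 4 at pre-pigment and 0 at either ommochrome stage. Random sets of 4 libraries gave a median of 0 and at most 7. No transcript met the same rule for the 8 libraries of either morph.

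The tests of a shared morph effect and of the number 1 as a batch were chosen after the result was seen, except the quantile test. So were those of the transcripts low in Rosa early ommochrome and of transcripts picked from the larvae alone. The counts of other splits and the other tests on Rosa larva replicate 2 were written before theirs. However, the rule that left the test of age on its 111 transcripts (below) undecided was set after that result was seen.

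Other splits of the libraries were refitted. Of 35 splits of the 8 larval and pre-pigment libraries, with morphs pooled, 1 (the real split) gave as many calls as the real 4530, and the highest other gave 7. Of 35 splits of the pre-pigment and early ommochrome libraries, 1 reached the real 120, and the highest other gave 4. The real split thus ranked 1 of 35 at both steps, the strongest result that 35 splits allow. Mixed splits leave stage differences inside their groups, which lowers their counts. Chance is therefore made unlikely but not excluded. For early to late ommochrome the real split gave 0, which 35 of 35 splits reach by construction, so this count does not weigh chance. The highest other split gave 105. It set both Linea early libraries with the Rosa early and late libraries numbered 1, so it follows stage in Linea and the replicate number in Rosa. This split was singled out as the highest after the counts were seen. Whether its count reflects a structure of the samples was not tested. For the averaged morph difference, 6 of 100 within-stage assignments gave at least the real 2 calls, so chance is not excluded. The highest gave 23 and set the 6 pupal libraries numbered 1 against their partners.

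A hypothesis of a common Rosa against Linea effect at every stage was tested by the mean correlation of the stage-wise differences. The real assignment gave -0.012, and 376 of 648 within-stage assignments gave at least as much, the highest 0.14. The tables argue against an effect shared by all 4 stages that covers many transcripts and is large beside the spread. A shared effect in few transcripts would hardly move this correlation and stays open. Morph effects limited to a stage stay open.

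Pupal libraries numbered 1 deviated from their partners in a shared direction. In all 6 groups 1405 transcripts moved the same way, where 494 are expected by chance. The overall distribution of values is argued against as the cause, since the mean correlation of the within-group differences was 0.106 and stayed at 0.104 after quantile normalization. A library batch may be the source, but 2 of 32 sign arrangements gave a mean correlation this high. The other reversed Linea early ommochrome and gave 0.132 and 1445 transcripts, so a batch cannot be told apart from chance or from unrecorded age; no biological explanation was tested.

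A group of 20 abundant transcripts was picked as far lower in both Rosa early ommochrome libraries than in the Linea early, Rosa pre-pigment and Rosa late libraries. The group's median was also high in the Linea pre-pigment and late libraries, which were not used to pick it. JC_0091645 was at 634 ± 554 scaled RPKM in Rosa and 36400 ± 19000 in Linea early ommochrome (SD, n = 2 each). Yet 0 of the 20 passed the adjusted threshold for that difference, and the mirror-image rule found 0 transcripts low in Linea. Library scaling is small beside the gap between Rosa and Linea in this group. Its log2 factors were 0.502 and 0.022 in the Rosa early libraries and -0.219 and -0.698 in the Linea ones. The median log2 difference of -4.65 in RPKM as deposited was bound by the picking to stay large, so it is no separate test. A larval label is argued against by a correlation of the other transcripts that was 0.188 higher with pupal than with larval libraries. A candidate explanation is a shared source, such as cells carried along in varying amount, or a shared regulator: the median pairwise correlation of deviations from the stage mean was 0.67 in the 8 libraries not used to pick the group (larvae, and Linea pre-pigment and late ommochrome); because 19 of the 20 rose from larva to pre-pigment, random groups were matched on abundance and on that change, and 1 of 10000 was as high (median 0.29, 95th percentile 0.47). Those 2 explanations and a morph effect at this stage remain open, since transcripts have no names here.

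Rosa larva replicate 2 held 111 transcripts above 20 RPKM at over 10 times any other library's value plus 1, against at most 9 in any other library, and they made up 10.2% of its summed RPKM. Linea risers were higher and Linea fallers lower in it than in Rosa larva replicate 3. The medians differed by 0.64 log2 units, as a larva older than replicate 3 could give. The library was not nearer to pupal wings than every larva. Its Spearman correlations with Linea pre-pigment replicates 1 and 2 and Rosa pre-pigment replicate 2 were 0.538, 0.562 and 0.583. Linea larva replicate 3 had 0.548, 0.603 and 0.604 with them. With Rosa pre-pigment replicate 1 the order was reversed, at 0.492 against 0.461. The 111 transcripts were mostly not raised at pre-pigment. Their median there was -0.25 log2 units relative to the other larvae (quartiles -0.81 and -0.05), with room for a 2-fold rise in 111 of 111. Of the 111, 6 were at least 2-fold higher. Picking from the larvae alone gave 195 transcripts (median 0.06, quartiles -0.35 and 1.6). The 84 that the pupal libraries had removed had a median of 1.67, which is bound by their removal and is no test of age. Because the picking of the 111 left out transcripts high in pupal wings, whether age is their source cannot be told. Material of another organism or tissue may also be the source and stays open, since the 111 reached 1 RPKM in a median of 2 of the 15 other libraries. The count of larval morph differences was 31 without this library.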
